A study of Homo sapiens with 14 samples.

How the data were processed

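The deposited files hold 2 tables of raw counts per gene, 1 with the vehicle, R1881, darolutamide 24 h and DaroR libraries (58735 lines, Ensembl identifiers) and 1 with the siRNA libraries of DaroR (60606 lines, gene symbols). Before deposition, per the labels, the authors made the counts with FastQC, Trim Galore, BWA and featureCounts against hg38, and the labels also name DESeq2. No versions, roles or order are stated there. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The values themselves are whole numbers with differing totals, as raw counts have, and no normalization was found in them.

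Columns were tied to samples by name. In the first table the columns named for castration-resistant prostate cancer were assigned to the DaroR group, because the labels call DaroR hormone non-sensitive, the siRNA samples have their own columns and no other group was left. In the second table both siGATA2 columns carry the same name, so they were taken as a group without replicate numbers, in the order of the file. No column was left over (0 unused). The 14 libraries form 7 groups of 2.

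Identifiers of the first table were matched to symbols through the reference gene tables (56513 of 58735, 96.2%), and 1296 lines shared a symbol with another line. They were tested as separate genes. Coordinates are whole-gene spans. Genes with near-identical copies (the UGT2B and AKR1C families, ORM1 and ORM2, SLC2A3, histone genes, MAGEA4, TRGC1 and the pseudogenes EEF1A1P6 and OCLNP1) may have gained or lost reads to their relatives.

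Each table was fitted by itself in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM, quasi-likelihood F test with robust dispersion, group as the only factor, 4 residual degrees of freedom in the first table and 3 in the second). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and a gene below it is described as called. A positive log2 fold change means higher in the group named first. The tables were never joined in a fit, since they were counted apart. The steps were tested on simulated data with 100 changed genes per effect size built from the same libraries. In the first, 86 of 100 genes at a log2 fold change of 1 and 100 of 100 at 2 were recovered, with 13 false calls among 14243 genes. In the second, the numbers were 43, 83 and 12 among 20118 genes. The changed genes were drawn only from genes above a minimum expected count, so recovery of genes with few counts was not measured. Within groups, the ratio of replicate differences to counting error (chi-square per degree of freedom) was 12.0 for R1881, 27.5 for vehicle, 20.2 for darolutamide, 4.80 for DaroR, 15.3 for siCtl, 161 for siAR and 9.12 for siGATA2.

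Where a group had a count of 0, the fold is given as a bound against 3 counts over the group, both libraries together. With 1 to 3 counts over the group it is a ratio with a 95% counting interval. Bounds and intervals cover counting error only. CPM for named genes use TMM-scaled library sizes, while CPM for genes absent from a group, for GATA2-AS1 and for AR and GATA2 as a percentage of siCtl use library totals.

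The genes to be named were fixed by a rule before the data were examined: 6 key genes always, the 8 largest fold changes per direction among called genes with at least 10 CPM in the higher group and libraries that did not overlap (5 per direction for siGATA2 against siAR), up to 4 members of each list by adjusted p, and genes called in DaroR and oppositely in siGATA2. Clone names, LOC numbers, ribosomal pseudogenes and antisense names were left out. The text prints a part of these. It mostly leaves out list members whose call was lost when 1 library was left out, a selection made after the values were seen, and members named outside the rule were chosen after their values were seen too.

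The 22 gene lists (androgen-induced and androgen-repressed genes, AR cofactors, GATA family, glucocorticoid receptor, androgen synthesis, cholesterol and fatty acids, G1/S, G2/M, apoptosis, p53, neuroendocrine, luminal, basal, mesenchymal, ER and integrated stress, interferon, NF-kB, immediate early, hypoxia, drug transport and IGF) and 5 check lists (stromal and immune cells, AR-negative lines, ribosomal proteins, mitochondrial transcripts, histones) were also fixed before the data were examined. Some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values (preset correlation 0.01), adjusted over all lists and comparisons, with an estimated correlation and fry as alternatives. Members were also adjusted over the list alone. Genes changed at least 2-fold with R1881 and in DaroR were followed in the second table through 14910 shared symbols, with camera and 2-sided Fisher's exact tests. Overlaps between comparisons that share control libraries are given beside the expectation for independent lists and 20 simulations without an effect.

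Alternatives planned before the data were examined were DESeq2 1.42.0, library totals or RLE size factors in place of TMM, no filter or a CPM of at least 1 in 2 libraries, a threshold of 0.01, a minimum log2 fold change of 1, only the groups compared in the fit, the replicate number as a block, and each library left out in turn. Leaving out mitochondrial genes, and a separate control library for each of a pair of comparisons, were added after the data were seen.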

Results

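Messenger RNA was sequenced from LNCaP cells, a line derived from a lymph node metastasis of human prostate cancer that carries the androgen receptor (AR) and depends on it. The 14 libraries, each made from polyadenylated RNA, fell into 7 groups of 2. LNCaP cells had received vehicle (DMSO), the synthetic androgen R1881 at 1 nM, or the AR antagonist darolutamide at 10 µM, each for 24 h. A resistant line, DaroR, had been kept in 10 µM darolutamide for 12 months. DaroR cells in 10 µM darolutamide had also been transfected with a control siRNA (siCtl), an siRNA against AR (siAR) or an siRNA labelled as directed against the transcription factor GATA2 (siGATA2). All cells grew in serum, so the vehicle cells were not free of androgen. The columns used here as DaroR are named for castration-resistant prostate cancer, and they were assigned because DaroR is the hormone-insensitive group without other columns. The labels do not say whether the libraries of a group came from separate cultures, so the edgeR p-values measure only the spread between these libraries, which may be technical. Those of camera with the preset correlation and of Fisher's exact test compare genes of a set with other genes. They measure the scatter among genes and do not show how a result would vary between cultures. Total counts per library ranged from 16846233 to 26139618 in the table with vehicle, R1881, darolutamide and DaroR (15649 genes tested) and from 36929496 to 54668696 in the table of siRNA libraries (21310 genes tested). Levels below are in CPM (counts scaled to a common library size), mean ± SD with n = 2 libraries in each group.

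The genes followed through all comparisons were AR and GATA2, the targets of the siRNAs, and the AR targets KLK3 (prostate-specific antigen), FKBP5 (a co-chaperone of steroid receptors), TMPRSS2 (a membrane serine protease) and NKX3-1 (a prostate homeobox factor). In GRCh38.p14, the assembly also called hg38, the gene AR spans positions 67544021 to 67730619 of chromosome X and GATA2 spans 128479422 to 128493201 of chromosome 3. KLK3 lies on chromosome 19 at 50854915 to 50860764, FKBP5 on chromosome 6 at 35573590 to 35728583, TMPRSS2 on chromosome 21 at 41464305 to 41508158, and NKX3-1 on chromosome 8 at 23678693 to 23682938. Each is protein-coding, and its counts were summed over the gene.

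The effect of AR activation was measured by comparing R1881 with vehicle. FKBP5 rose 15.7-fold, from 100.2 ± 7.32 to 1577 ± 79.7 CPM (log2 fold change 3.98 ± 0.13 SE, edgeR adjusted p = 1.32e-13), and TMPRSS2 rose 5.36-fold, from 223 ± 28.0 to 1195 ± 45.2 CPM. NKX3-1 rose 2.43-fold to 1372 ± 54.5 CPM and KLK3 1.55-fold to 2785 ± 272 CPM (edgeR adjusted p = 0.00306). AR stood at 206 ± 18.8 CPM with R1881 and 228 ± 22.8 CPM with vehicle (edgeR adjusted p = 0.452). GATA2 stood at 51.3 ± 3.12 and 57.4 ± 11.8 CPM (edgeR adjusted p = 0.407), and without Vehicle replicate 2 it passed the threshold as lower (edgeR adjusted p = 0.0447). The largest rises included STEAP4, a metalloreductase (149-fold, to 181 ± 9.15 CPM), NDRG1, a growth and stress response gene (39.3-fold, to 1554 ± 86.9 CPM), the transcription factor MAF (37.9-fold) and ANGPT2, a ligand of the endothelial receptor TIE2 (33.4-fold, to 37.4 ± 8.96 CPM). The largest falls included ABCA12, a lipid transporter (10.4-fold, to 1.00 ± 0.268 CPM), SLC7A5, a transporter of large neutral amino acids (8.80-fold, to 1.52 ± 0.241 CPM) and DDC, aromatic amino acid decarboxylase (7.25-fold, to 12.6 ± 0.110 CPM).

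All 26 measured androgen-induced targets rose with R1881, over all genes and when adjusted over the list alone (camera adjusted p = 3.53e-35, adjusted p = 0.0155 with an estimated correlation). All 9 measured androgen-repressed genes fell, by both adjustments (camera adjusted p = 3.60e-09, adjusted p = 0.325 with an estimated correlation). Among them were UGT2B17 (7.33-fold) and UGT2B15 (5.34-fold), which conjugate androgens and are uncertain because the UGT2B genes are near-identical, and CAMK2N1, an inhibitor of CaM kinase II (4.57-fold). Of 24 genes of cholesterol and fatty acid synthesis, 14 rose, 1 fell and 9 were not called, with the same counts adjusted over the list alone (camera adjusted p = 3.55e-06, adjusted p = 0.511 with an estimated correlation). FASN, fatty acid synthase, rose 4.26-fold to 2000.2 ± 107 CPM and HMGCS1, an early enzyme of the sterol pathway, rose 2.38-fold. AR cofactors and pioneer factors rose for 9 of 14 genes, also when adjusted over the list alone (camera adjusted p = 2.69e-05, adjusted p = 0.384 with an estimated correlation), with SPDEF, a prostate ETS factor, up 4.26-fold and FOXA1 up 1.43-fold. Of the glucocorticoid receptor and its targets, 7 rose and 1 fell by both adjustments (camera adjusted p = 1.33e-04, adjusted p = 0.214 with an estimated correlation). SGK1, a kinase induced by steroid hormones, rose 21.0-fold. The member that fell was the receptor itself, NR3C1, which had very few counts in either group (0 and 1 with R1881, 6 and 14 in vehicle). The luminal keratins KRT8 and KRT18 rose 6.58-fold and 3.44-fold, while the luminal list as a whole (4 rose, 2 fell, 8 not called; 4 and 4 adjusted over the list alone) was not called by camera (adjusted p = 0.529), its median below 0 and its mean above.

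Cell cycle genes were lower with R1881. Replication-dependent histones stood the other way, at 1298 and 1304 CPM against 964 and 1198 CPM in vehicle. Of 19 genes of G1/S and DNA replication, 17 fell and 2 were not called (18 fell adjusted over the list alone; camera adjusted p = 2.69e-16, adjusted p = 0.175 with an estimated correlation). PCNA, the replication clamp, fell 2.62-fold to 125 ± 1.59 CPM and the helicase subunit MCM4 fell 2.55-fold. Of 24 genes of G2/M and mitosis, 20 fell and 4 were not called (21 fell adjusted over the list alone; camera adjusted p = 3.79e-14, adjusted p = 0.175 with an estimated correlation), among them cyclin B2, CCNB2 (2.23-fold) and the spindle checkpoint kinase BUB1B (2.11-fold). In all, edgeR called 4502 genes, 2350 higher and 2152 lower, 1356 of them by at least 2-fold. Without R1881 replicate 1 it called 2535.

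Darolutamide for 24 h was compared with vehicle to measure acute AR blockade. NKX3-1 fell 9.62-fold, from 565 ± 35.0 to 58.7 ± 2.08 CPM (log2 fold change -3.27 ± 0.13 SE, edgeR adjusted p = 1.14e-11), KLK3 fell 6.05-fold to 297 ± 53.2 CPM, TMPRSS2 4.92-fold to 45.2 ± 13.0 CPM and FKBP5 2.42-fold to 41.5 ± 3.44 CPM. AR fell 1.51-fold to 151 ± 30.5 CPM (edgeR adjusted p = 0.00711), a call lost without Daro24h replicate 1 (edgeR adjusted p = 0.0663). GATA2 stood at 47.6 ± 0.896 CPM against 57.4 ± 11.8 CPM (edgeR adjusted p = 0.203), and it passed the threshold as lower without Vehicle replicate 2 (edgeR adjusted p = 0.0232). The largest falls included TRPM8, a cold-sensing cation channel (35.8-fold, to 0.837 ± 0.173 CPM), CHRNA2, a nicotinic receptor subunit (23.3-fold), KLK2, a kallikrein (10.1-fold, to 12.2 ± 0.241 CPM) and HPGD, a prostaglandin-degrading enzyme (7.99-fold). The largest rises included OPRK1, the kappa opioid receptor (6.28-fold, to 77.9 ± 33.8 CPM), MAN1A1, a mannosidase of the Golgi (6.10-fold), the cell adhesion gene AMIGO2 (3.90-fold) and ID1, an inhibitor of bHLH factors (3.21-fold, to 40.9 ± 0.0821 CPM).

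Of the 26 androgen-induced targets, 24 fell and 2 were not called with darolutamide, and all 26 fell when adjusted over the list alone (camera adjusted p = 4.84e-40, adjusted p = 0.0155 with an estimated correlation). SLC45A3, a prostate solute carrier, fell 5.22-fold. Of 9 androgen-repressed genes, 5 rose and 4 were not called, and 8 rose adjusted over the list alone (camera adjusted p = 1.12e-09, adjusted p = 0.315 with an estimated correlation). CAMK2N1 rose 2.98-fold and DDC 2.08-fold. Cholesterol and fatty acid genes fell for 12 of 24 and rose for 1 (15 and 1 adjusted over the list alone; camera adjusted p = 3.53e-08, adjusted p = 0.394 with an estimated correlation). DHCR24, which makes the last reduction in cholesterol synthesis, fell 2.46-fold to 805 ± 179 CPM and ACACA, acetyl-CoA carboxylase, fell 1.83-fold. Cell cycle genes fell here too, 15 of 19 for G1/S (17 adjusted over the list alone; camera adjusted p = 1.15e-17, adjusted p = 0.175 with an estimated correlation) and 14 of 24 for G2/M (17 adjusted over the list alone; camera adjusted p = 9.61e-12, adjusted p = 0.178 with an estimated correlation). MCM4 fell 2.10-fold and the mitotic kinase PLK1 fell 1.87-fold. MYC fell 1.60-fold and NFKB2, an NF-kB subunit, fell 1.66-fold to 9.41 ± 0.0701 CPM, while SESN1 and TP53INP1, p53 targets, rose 1.89-fold and 1.73-fold. DDIT3, a transcription factor of the stress response, rose 2.33-fold.

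Smaller shifts of 4 further lists depended on single libraries. AR cofactors (3 of 14 fell, also adjusted over the list alone) had a camera adjusted p = 0.0375 (adjusted p = 0.541 with an estimated correlation), which became 0.679 without Vehicle replicate 1 and 0.0952 without Daro24h replicate 1. For p53 targets (3 of 15 rose, also adjusted over the list alone) the camera adjusted p = 0.0365 (adjusted p = 0.516 with an estimated correlation) became 0.343 without Vehicle replicate 1 and 0.0942 without Daro24h replicate 2. For ER stress and integrated stress response genes (5 rose and 1 fell of 18, 7 and 2 adjusted over the list alone) the camera adjusted p = 0.0416 (adjusted p = 0.663 with an estimated correlation) became 0.498 and 0.451 without the same libraries, and the call was also lost with library totals only. For hypoxia and glycolysis (4 of 15 fell, 7 adjusted over the list alone) the camera adjusted p = 0.0209 (adjusted p = 0.541 with an estimated correlation) became 0.118 without Vehicle replicate 2 and 0.0738 without Daro24h replicate 1. In all, edgeR called 1975 genes, 806 higher and 1169 lower (633 and 1710 with library totals alone), and 1218 when only the vehicle and darolutamide libraries entered the fit.

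The responses to R1881 and to darolutamide at 24 h shared vehicle libraries. Of the genes called in both, 353 were higher with R1881 and lower with darolutamide and 266 were lower and then higher, against 176 and 111 for independent lists. Another 96 were higher and 260 lower in both, against 121 and 161 for independent lists. In 20 simulations of unchanged groups against these controls, the mean number called in both was at most 0.05 in any direction. No gene has an effect in such a simulation, so it does not show how shared controls alter the overlap among changed genes. The covariance of the fold changes was 0.0338, below the 0.125 that shared controls alone gave. Without R1881 replicate 1 the genes called in opposite directions numbered 395 in place of 619. With each comparison set against its own vehicle library, in either order, the genes called in opposite directions numbered 604 and 686 and the covariance was -0.12 and -0.14.

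The DaroR line was compared with vehicle to find what long exposure to the drug had changed. AR rose 2.64-fold, from 228 ± 22.8 to 602 ± 10.2 CPM (log2 fold change 1.40 ± 0.14 SE, edgeR adjusted p = 7.40e-08), and GATA2 rose 2.53-fold, from 57.4 ± 11.8 to 145 ± 2.69 CPM (log2 fold change 1.34 ± 0.13 SE, edgeR adjusted p = 9.00e-08). KLK3 fell 16.3-fold to 110.4 ± 1.25 CPM, FKBP5 5.75-fold to 17.4 ± 0.216 CPM, NKX3-1 2.96-fold to 191 ± 7.16 CPM and TMPRSS2 2.16-fold to 103 ± 1.98 CPM. NRXN1, a presynaptic adhesion gene, rose from 0.125 ± 0.177 to 536 ± 30.9 CPM, and UNC13C, a vesicle priming gene, rose to 190 and 213 CPM. Each had counts in only 1 vehicle library, so the size of the fold is not given: the log2 fold change went from 11.03 to 16.48 for NRXN1 and from 8.86 to 15.06 for UNC13C, depending on the vehicle library left out. ETV1, an ETS transcription factor whose locus is rearranged in LNCaP, fell from 213 ± 10.3 CPM to a count of 0 in both DaroR libraries, at least 4131-fold against 3 counts over the group. Scaling set the reference point here, since TMM moved the DaroR fold changes by 0.37 against library totals, and every change is relative to that.

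Other genes at the extremes of DaroR included the neurodevelopmental adaptor DAB1 (from 0.123 ± 0.085 to 84.0 ± 5.85 CPM, log2 fold change from 8.80 to 10.26 by the vehicle library left out), COL3A1, a fibrillar collagen (611-fold higher, to 249 ± 17.3 CPM) and the matrix gene CCDC80 (from 0.280 ± 0.137 to 98.6 ± 4.52 CPM, 8.01 to 9.03). BASP1, a membrane protein of nerve endings, was at 47.6 ± 2.90 CPM, 1534-fold above vehicle (95% counting interval 275 to 60592). MYO7A, an unconventional myosin, and NTS, neurotensin, had no count in vehicle and were at least 133-fold and at least 120.3-fold higher. Of the genes that fell, ADAM7, FUCA2 (a fucosidase) and PSMD5 (a proteasome assembly chaperone) had no count in DaroR and were at least 717-fold, 294-fold and 219.9-fold lower. EPHA3, an ephrin receptor, fell 5501-fold (95% counting interval 987 to 217362), LPAR3, a lysophosphatidic acid receptor, 3421-fold (946 to 28261) and PTGFR, the prostaglandin F receptor, 1733-fold. RIPOR2 fell 2175-fold (95% counting interval 389.7 to 85993).

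**Figure D1:**
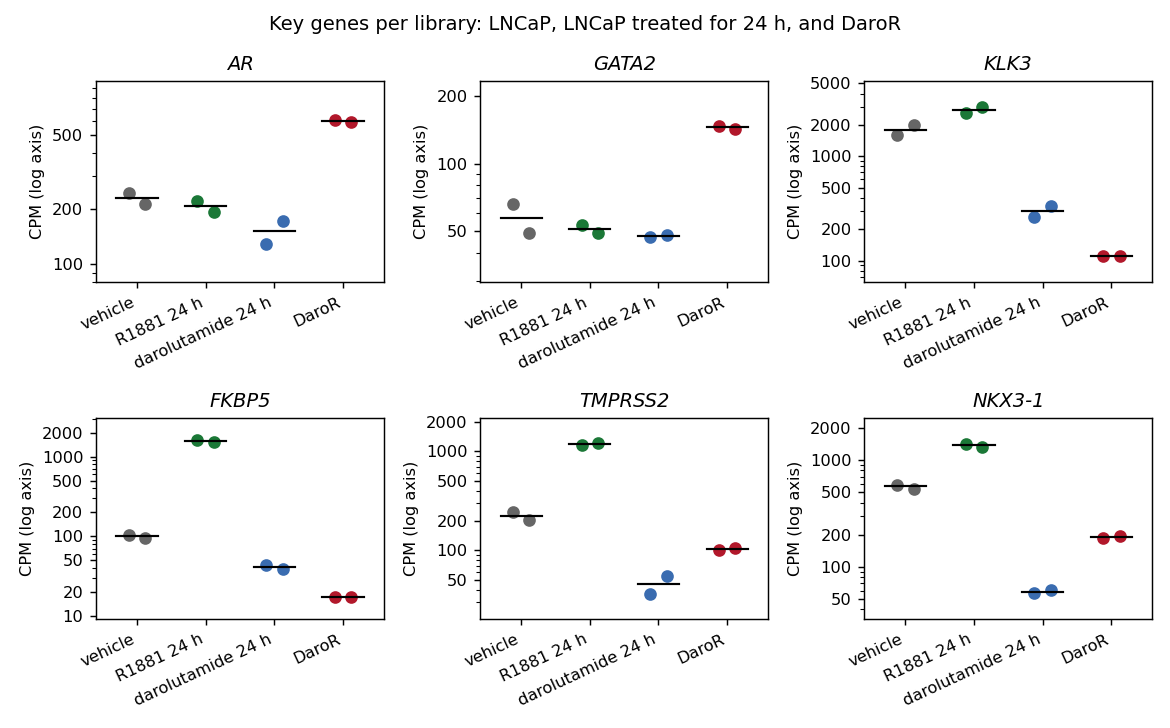
Level of AR, GATA2, KLK3, FKBP5, TMPRSS2 and NKX3-1 (y axis, CPM on a log scale) in vehicle, R1881 24 h, darolutamide 24 h and DaroR (x axis); each point is 1 of the 2 libraries of a group and the line is their mean. AR and GATA2 stand highest in DaroR (602 and 145 CPM), whereas KLK3 and FKBP5 are lowest there (110.4 and 17.4 CPM) and TMPRSS2 and NKX3-1 are lowest after 24 h of darolutamide (45.2 and 58.7 CPM).

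Most androgen-induced targets were lower in DaroR than in vehicle: 22 of 26 fell, 1 rose and 3 were not called, with the same counts adjusted over the list alone (camera adjusted p = 3.60e-09, adjusted p = 0.169 with an estimated correlation). SLC45A3 fell 18.9-fold, and NDRG1, named after its value was seen, was the member that rose. The androgen-repressed genes moved both ways (2 rose, 4 fell, 3 not called, by both adjustments; camera adjusted p = 0.603). DDC rose 2.56-fold and OPRK1 5.38-fold, while UGT2B17 and UGT2B15 fell 22.2-fold and 17.5-fold. Genes of androgen synthesis and metabolism fell for 9 of 14 and rose for 3, by both adjustments (camera adjusted p = 0.0216, adjusted p = 0.516 with an estimated correlation). The 9 include 4 UGT2B genes, which inactivate androgens, and HSD17B11, a 17β-hydroxysteroid dehydrogenase (8.33-fold). The members that rose were AKR1C1, AKR1C2 and AKR1C3, aldo-keto reductases that act on steroids, named after their values were seen: AKR1C3, which makes testosterone from androstenedione, rose 17.3-fold to 4.93 ± 0.141 CPM, and the near-identical AKR1C1 and AKR1C2 are uncertain. Cholesterol and fatty acid genes fell for 17 of 24 and rose for 1 (19 and 1 adjusted over the list alone; camera adjusted p = 8.53e-06, adjusted p = 0.516 with an estimated correlation). DHCR24 fell 7.03-fold and SCD, the stearoyl-CoA desaturase, 3.87-fold to 455 ± 3.43 CPM.

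Cell cycle genes were far lower in DaroR. For G1/S and DNA replication, 18 of 19 fell by both adjustments (camera adjusted p = 8.30e-11, adjusted p = 0.214 with an estimated correlation), with RRM2, a ribonucleotide reductase subunit, down 8.17-fold and CDC45, a replication helicase factor, down 15.1-fold. For G2/M and mitosis, 21 of 24 fell and 2 rose by both adjustments (camera adjusted p = 2.28e-13, adjusted p = 0.175 with an estimated correlation), with BIRC5, survivin, down 9.89-fold to 26.5 ± 3.64 CPM and cyclin A2, CCNA2, down 14.5-fold. The members that rose, CENPF and CENPE, named after their values were seen, are kinetochore proteins. Hypoxia and glycolysis genes fell for 10 of 15 and rose for 2 by both adjustments (camera adjusted p = 0.0259, adjusted p = 0.559 with an estimated correlation). LDHA, lactate dehydrogenase A, fell 4.76-fold to 326 ± 7.44 CPM and VEGFA, the angiogenic factor, rose 3.49-fold.

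The other lists were not called by camera in DaroR, although their members moved. AR cofactors and pioneer factors rose for 9 of 14 and fell for 3 by both adjustments (camera adjusted p = 0.0767), but passed with library totals only and without Vehicle replicate 1 (adjusted p = 0.0199). GRHL2, a pioneer factor of epithelia, rose 2.56-fold to 114 ± 1.14 CPM and the corepressor NCOR1 2.92-fold. Of the GATA family and partners, 3 of 4 rose by both adjustments, too few for a set test. GATA6 reached 9.02 ± 0.167 CPM, 1.94-fold above vehicle. The glucocorticoid receptor list had 2 genes up and 2 down of 8 by both adjustments (camera adjusted p = 0.482), and the receptor itself, NR3C1, rose from 0.615 ± 0.338 to 13.4 ± 0.228 CPM (log2 fold change from 3.96 to 5.13 by the vehicle library left out). Its target TSC22D3 rose 3.44-fold. Neuroendocrine and neural genes rose for 4 of 6 and fell for 2 by both adjustments (camera adjusted p = 0.517), with ENO2, neuronal enolase, at 28.5 ± 1.76 CPM (2.05-fold higher) and PEG10 2.92-fold higher. Of 14 luminal genes, 5 rose and 7 fell by both adjustments (camera adjusted p = 0.810), with KRT19 down 19.7-fold and ELF3 up 2.54-fold. Of 4 basal genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone), too few for a set test, and the integrin ITGB4 was higher, at 5.04 ± 0.739 against 0.752 ± 0.977 CPM (by the vehicle library left out, 3.48-fold or a log2 fold change of 6.24). Of 8 mesenchymal genes, 3 rose and 3 fell by both adjustments (camera adjusted p = 0.727, with a mean below 0 and a test directed up). FN1, fibronectin, rose 16.5-fold to 1546 ± 2.97 CPM and VIM, vimentin, 7.72-fold, while SPARC, a matrix glycoprotein, had no count in DaroR and was at least 58.1-fold lower.

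For stress response genes, 7 rose and 6 fell of 18 by both adjustments (camera adjusted p = 0.603). DDIT3 rose 15.7-fold to 78.2 ± 1.41 CPM and ATF3, a stress-induced transcription factor, 3.61-fold. For p53 targets, 6 rose and 5 fell of 15 by both adjustments (camera adjusted p = 0.698, median below 0 and mean above), with SESN1 up 2.42-fold and the cytokine GDF15 up 2.08-fold. For apoptosis regulators, 3 rose and 7 fell of 17 by both adjustments (camera adjusted p = 0.375, with a mean just above 0 and a test directed down). HRK, a BH3-only protein, rose to 4.96 ± 0.876 CPM (log2 fold change from 4.68 to 6.22 by the vehicle library left out), XIAP, a caspase inhibitor, rose 2.17-fold and BAK1, an effector of mitochondrial permeability, fell 2.62-fold. For interferon response genes, 2 rose and 6 fell of 13 by both adjustments (camera adjusted p = 0.107), with OAS3, an antiviral synthetase, down 9.30-fold and IFIT1 down 6.27-fold. For NF-kB genes, 4 rose and 2 fell of 8 by both adjustments (camera adjusted p = 0.856), with NFKB2 up 1.82-fold and its inhibitor NFKBIA down 2.10-fold. Of 8 immediate early genes, 3 rose, 2 adjusted over the list alone (camera adjusted p = 0.196), with JUN up 2.60-fold. For drug transport, 3 rose and 3 fell of 7 by both adjustments (camera adjusted p = 0.965), with the oxidoreductase NQO1 down 1.86-fold and the efflux pump ABCC1 up 1.56-fold. For the IGF axis, 4 rose and 3 fell of 8, 5 and 3 adjusted over the list alone (camera adjusted p = 0.536), with IGFBP3, an IGF-binding protein, up 12.3-fold to 135 ± 5.35 CPM.

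**Figure D2:**
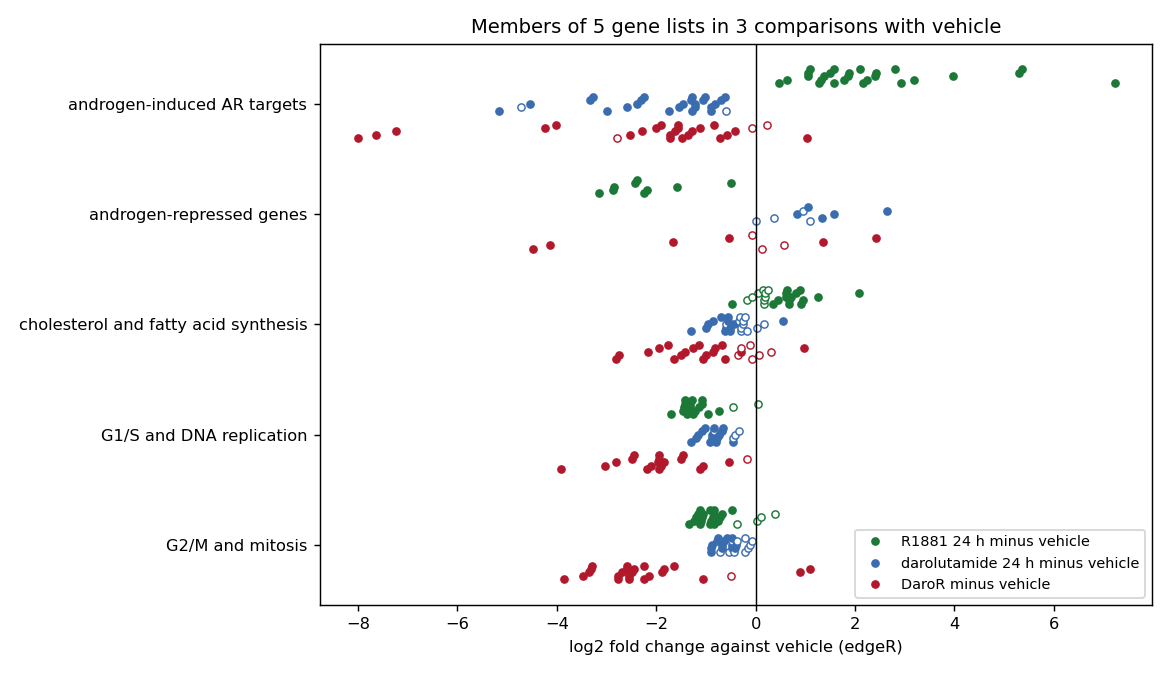
Log2 fold change against vehicle (x axis) of the measured members of 5 lists in R1881, darolutamide 24 h and DaroR. The lists (y axis) are androgen-induced, androgen-repressed, cholesterol and fatty acid synthesis, G1/S and G2/M. Each point is 1 gene, filled where edgeR adjusted p was under 0.05. All 26 androgen-induced genes lie to the right of 0 with R1881, and 24 of 26 (darolutamide 24 h) and 22 of 26 (DaroR) are called to its left. Fitted values of genes with very few counts depend on the prior.

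In all, edgeR called 9608 genes between DaroR and vehicle, 4930 higher and 4678 lower (7125 and 2952 with library totals alone), 5228 of them by at least 2-fold. Several measures of the libraries moved with DaroR. Mitochondrial transcripts made up 5.99% and 6.0% of counts in the DaroR libraries, against 7.79% to 16.0% in the other libraries of the table. Replication-dependent histones stood at 307 and 313 CPM against 964 to 1304 CPM. Marker genes of stromal, endothelial and immune cells summed to 299 and 326 CPM against 12.1 to 17.6 CPM, and to 9.41 and 8.63 CPM without COL3A1. Markers of AR-negative carcinoma lines summed to 1.42 to 3.99 CPM in all 8 libraries, and ribosomal protein genes made up 9.32% to 13.5% of counts. With R1881 these markers were at 3.15 and 3.99 CPM, against 1.42 and 1.49 CPM in vehicle. The ribosomal protein share was 9.34% and 9.32% with R1881 against 11.2% and 12.5% in vehicle.

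Of the genes called with R1881 and in DaroR against the same vehicle libraries, 1093 were higher and 1286 lower in both, against 740 and 643 for independent lists. Genes higher with R1881 and lower in DaroR numbered 564 and the reverse 332, against 702 and 678 for independent lists. The covariance was 0.232 against a simulated 0.124. For darolutamide at 24 h and DaroR, 377 genes were higher and 705 lower in both, against 254 and 349 for independent lists, and 194 and 209 went opposite ways, against 241 and 368. Here the covariance was 0.556 against a simulated 0.125. The simulations of unchanged groups gave a mean of 0 genes called in both, which again does not measure the overlap among changed genes. With a separate vehicle library for each comparison, in either order, R1881 and DaroR shared 1672 and 2237 genes moving the same way (covariance 0.08 and 0.22). Darolutamide and DaroR shared 691 and 1098 (covariance 0.40 and 0.56), so part of each excess may come from the shared libraries. The shortfall of opposite calls was kept in each order for only some directions. In 1 order it became an excess for genes lower with darolutamide and higher in DaroR. The same held for genes higher with R1881 and lower in DaroR. For genes lower with R1881 and higher in DaroR it was kept in both orders. Genes higher with darolutamide and lower in DaroR kept only a slight shortfall in both orders. Without R1881 replicate 1 the genes moving the same way with R1881 and in DaroR numbered 1299 in place of 2379.

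DaroR was also compared with 24 h of darolutamide, at the same drug concentration, to separate long from short exposure. AR was 3.99-fold higher in DaroR (602 ± 10.2 against 151 ± 30.5 CPM, edgeR adjusted p = 1.19e-09) and GATA2 3.04-fold higher (145 ± 2.69 against 47.6 ± 0.896 CPM, edgeR adjusted p = 1.06e-08). TMPRSS2 was 2.28-fold and NKX3-1 3.25-fold higher in DaroR than after 24 h of drug, while KLK3 and FKBP5 were 2.69-fold and 2.38-fold lower. TRPM8 was 34.2-fold higher, at 29.1 ± 2.12 CPM, and KLK2 4.15-fold higher, at 50.7 ± 2.95 CPM. Among the androgen-induced targets, 11 rose, 12 fell and 3 were not called, by both adjustments (camera adjusted p = 0.939, directed down where fry was directed up).

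AR cofactors rose for 9 of 14 and fell for 1 by both adjustments (camera adjusted p = 0.00777, adjusted p = 0.516 with an estimated correlation), with GRHL2 up 3.73-fold and NCOR1 up 3.63-fold. Androgen-repressed genes fell for 5 of 9 and rose for none by the adjustment over all genes (1 rose adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.541 with an estimated correlation, 0.0551 without Daro24h replicate 2). UGT2B15 fell 44.1-fold and CAMK2N1 4.30-fold. Cholesterol and fatty acid genes fell for 15 of 24 and rose for 5 by both adjustments (camera adjusted p = 0.0145, adjusted p = 0.582 with an estimated correlation, and just above 0.05 without Daro24h replicate 2), with INSIG1, the sterol sensor partner, down 3.05-fold. Androgen synthesis and metabolism fell for 9 of 14 and rose for 3 by both adjustments (camera adjusted p = 0.0384, adjusted p = 0.384 with an estimated correlation). Of the cell cycle, 15 of 19 G1/S genes fell and 1 rose by both adjustments (camera adjusted p = 1.29e-05, adjusted p = 0.384 with an estimated correlation), and 21 of 24 G2/M genes fell and 2 rose by both adjustments (camera adjusted p = 8.44e-11, adjusted p = 0.214 with an estimated correlation). Cyclin B1, CCNB1, fell 5.56-fold to 81.5 ± 2.83 CPM. Interferon genes fell for 10 of 13 and rose for 1, 2 adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.384 with an estimated correlation), with ISG15, a ubiquitin-like modifier, down 2.24-fold. At the extremes, COL3A1 was 220.3-fold higher, NRXN1 was at 536 ± 30.9 against 0.195 ± 0.199 CPM (log2 fold change from 10.62 to 13.10 with a library left out), SLC22A3, an organic cation transporter, fell from 527 ± 47.8 to 0.245 ± 0.185 CPM (-12.09 to -10.43), and AGR2, a disulfide isomerase, had no count in DaroR and was at least 191-fold lower. In all, edgeR called 9503 genes, 4908 higher and 4595 lower (7490 and 2540 with library totals alone), where TMM moved fold changes by 0.44.

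The siRNAs were applied to DaroR to ask what AR and GATA2 maintain in the resistant cells, and their targets come first. AR was 254 and 279 CPM in the siAR libraries against 822 and 784 CPM in siCtl, a 3.01-fold fall (log2 fold change -1.59 ± 0.14 SE, edgeR adjusted p = 0.00579). GATA2 was 214 and 192 CPM in the libraries labelled siGATA2 against 196 and 228 CPM in siCtl (log2 fold change -0.07 ± 0.14 SE, edgeR adjusted p = 0.940). The measured GATA2 transcript therefore does not bear out the label, and the directions below are those of the libraries labelled siGATA2. The gene overlaps its antisense gene GATA2-AS1, and the strand of counting is not stated. The siAR libraries stood apart from each other: 1103 genes differed over 2-fold between them, against 7 to 104 in the other groups. KLK3 was 189.7 CPM in siAR replicate 1 and 1169 CPM in replicate 2, and KLK2 82.1 and 710.1 CPM, against 578 and 601 CPM and 703 and 736 CPM in siCtl.

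In siAR against siCtl, KLK4, a kallikrein induced by androgen, fell 3.40-fold to 79.6 ± 5.55 CPM (edgeR adjusted p = 0.00325), RELN, the secreted glycoprotein reelin, fell 3.55-fold to 156 ± 0.576 CPM and ZBTB16, a zinc finger factor induced by steroids, fell 3.14-fold to 51.7 ± 9.61 CPM. COLEC12, a scavenger receptor, rose 4.04-fold to 62.8 ± 8.62 CPM (edgeR adjusted p = 0.00325), TNFRSF19, a TNF receptor family member, rose 4.33-fold and COL5A2, a fibrillar collagen, rose 5.15-fold. COLCA1 rose 10.4-fold to 137 ± 67.0 CPM and CBLN2, a synaptic organiser, 7.89-fold. GATA2 stood at 351 ± 0.865 CPM against 212 ± 22.7 CPM (edgeR adjusted p = 0.0522). TMPRSS2 stood at 229 ± 74.9 against 465 ± 5.44 CPM (edgeR adjusted p = 0.0620), NKX3-1 at 329.6 ± 189 against 736 ± 24.1 CPM (0.160), FKBP5 at 91.0 ± 75.5 against 169 ± 8.75 CPM (0.546) and KLK3 at 679.6 ± 693 against 589 ± 16.3 CPM (0.944).

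Of 25 androgen-induced targets, 3 fell and 22 were not called in siAR, and 14 fell adjusted over the list alone (camera adjusted p = 4.34e-14, adjusted p = 0.516 with an estimated correlation). Androgen-repressed genes had no member called of 9, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0142, directed up, adjusted p = 0.384 with an estimated correlation). Interferon genes fell for 4 of 15, 8 adjusted over the list alone (camera adjusted p = 7.03e-08, adjusted p = 0.178 with an estimated correlation), with OAS3 down 2.35-fold and IFIT1 3.56-fold. Of 11 NF-kB genes, 1 fell, 3 adjusted over the list alone (camera adjusted p = 3.79e-05, adjusted p = 0.516 with an estimated correlation, 0.952 without siAR replicate 2). It was TNFAIP3, an inhibitor of NF-kB, down 2.43-fold to 10.1 ± 0.0510 CPM. Of 24 G2/M genes, 1 fell by both adjustments (camera adjusted p = 4.41e-07, adjusted p = 0.600 with an estimated correlation, 0.268 without siAR replicate 1), namely CENPF, down 1.97-fold. No G1/S gene was called (0 of 19 by edgeR, also adjusted over the list alone; camera adjusted p = 0.0793, and 4.82e-06 without siAR replicate 2). Of 15 p53 targets, SESN1 and TP53INP1 rose 2.12-fold and 1.78-fold and 13 were not called, with 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.939, with a median below 0 and a mean above, and 0.0219 without siAR replicate 1). SCD rose 1.92-fold to 676 ± 35.7 CPM. Mitochondrial transcripts made up 5.74% and 2.02% of counts in the siAR libraries against 3.47% and 4.42% in siCtl. Markers of AR-negative carcinoma lines summed to 34.6 and 6.03 CPM against 26.5 and 23.3 CPM, mostly through LAMB3, a laminin chain. Stromal, endothelial and immune markers summed to 34.6 CPM in both siAR libraries against 22.3 and 23.1 CPM (27.1 and 29.0 against 18.9 and 19.2 CPM without COL3A1), and ribosomal protein genes made up 5.31% and 7.66% of counts against 6.57% and 6.67%.

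In all, edgeR called 223 genes in siAR, 136 higher and 87 lower, and the count depended on single libraries. It was 0 without either siCtl library, where DESeq2 on all libraries called 1430 and 3601 genes had an unadjusted p under 0.05 in the edgeR fit, and 3607 and 6818 without siAR replicates 1 and 2. AR itself was no longer called without siCtl replicate 1 (log2 fold change -1.56, edgeR adjusted p = 0.345), without siCtl replicate 2 (-1.63, 0.329) or when only siAR and siCtl entered the fit (-1.59, 0.0668).

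**Figure D3:**
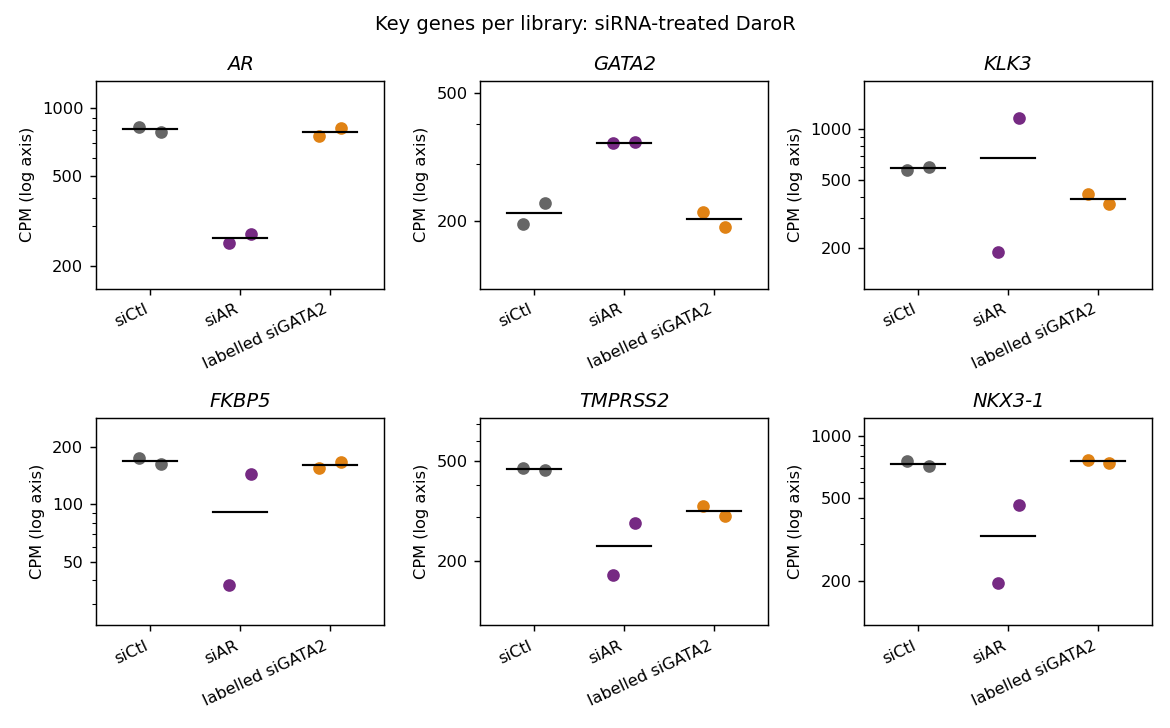
Level of the same 6 genes (y axis, CPM on a log scale) in DaroR with siCtl, siAR and the libraries labelled siGATA2 (x axis); each point is 1 of the 2 libraries of a group and the line is their mean. AR is lower in both siAR libraries (254 and 279 CPM against 784 and 822 in siCtl), GATA2 in the libraries labelled siGATA2 (192 and 214 CPM) lies level with siCtl (196 and 228 CPM), and the siAR libraries differ widely for KLK3 (189.7 and 1169 CPM).

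In the libraries labelled siGATA2, ITGB1, the integrin beta 1 subunit, fell 3.29-fold against siCtl, from 418 ± 33.1 to 127 ± 1.60 CPM (edgeR adjusted p = 0.0121), BZW2, a regulator of translation initiation, fell 3.39-fold to 11.8 ± 0.549 CPM and TMEM123 2.75-fold. PTDSS1, a phosphatidylserine synthase, fell 2.42-fold and SEPTIN3, a neuronal septin, 2.61-fold. GPR63, an orphan receptor, rose 2.83-fold to 44.2 ± 2.81 CPM (edgeR adjusted p = 0.0243), ARG2, the mitochondrial arginase, 2.53-fold to 319.6 ± 13.7 CPM, and PLEKHH1 2.20-fold. The histone gene H2BC21, which has near-identical copies, rose 2.30-fold. AR stood at 783 ± 47.9 against 803 ± 27.1 CPM, KLK3 at 391 ± 36.1 against 589 ± 16.3 CPM, TMPRSS2 at 317 ± 19.8 against 465 ± 5.44 CPM, FKBP5 at 160.4 ± 7.57 against 169 ± 8.75 CPM and NKX3-1 at 753 ± 13.1 against 736 ± 24.1 CPM, with edgeR adjusted p from 0.393 to 0.992. Among the androgen-induced targets, edgeR called 0 of 25, and 2 fell adjusted over the list alone (camera adjusted p = 0.289). KLK2, named after its value was seen, stood at 289 ± 7.82 against 719.6 ± 23.4 CPM. KLK2, KLK3 and TMPRSS2 were lower in both of these libraries than in either siCtl library, whereas FKBP5 and NKX3-1 overlapped. The fit takes in the spread of the siAR libraries, so the lack of calls does not show that these genes were unchanged.

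No cell cycle gene passed over all genes in these libraries (0 of 19 and 0 of 24 by edgeR), but 17 of 19 G1/S genes and 9 of 24 G2/M genes fell adjusted over the list alone. The lists were called down by camera (adjusted p = 3.48e-20 for G1/S and 4.19e-14 for G2/M; adjusted p = 0.511 and 0.516 with an estimated correlation). E2F1, a cell cycle transcription factor, stood at 22.6 ± 2.09 against 57.9 ± 9.60 CPM and MKI67, a proliferation marker, at 57.8 ± 6.26 against 102 ± 6.34 CPM. Replication-dependent histones stood the other way, at 320.2 and 336 CPM against 199.95 and 188 CPM in siCtl. Markers of AR-negative carcinoma lines summed to 35.4 and 31.2 CPM against 26.5 and 23.3 CPM, and ribosomal protein genes made up 5.66% and 5.46% of counts against 6.57% and 6.67%. Of 15 p53 targets, 1 fell, 4 adjusted over the list alone (camera adjusted p = 5.58e-06, adjusted p = 0.516 with an estimated correlation). It was BTG2, an antiproliferative gene, down 2.20-fold to 14.8 ± 1.06 CPM. Of 18 stress response genes none was called by edgeR, also adjusted over the list alone (camera adjusted p = 0.0150, directed down, adjusted p = 0.511 with an estimated correlation, 0.0912 without the second siGATA2 column). OAS3 fell 2.21-fold. FN1 stood at 1641 ± 27.8 against 3695 ± 120.2 CPM (edgeR adjusted p = 0.325). ARG2, PLEKHH1 and PIGH, which attaches glycan to lipid in GPI anchor synthesis and rose 2.05-fold, lie side by side on chromosome 14, between 67533290 and 67651708.

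**Figure D4:**
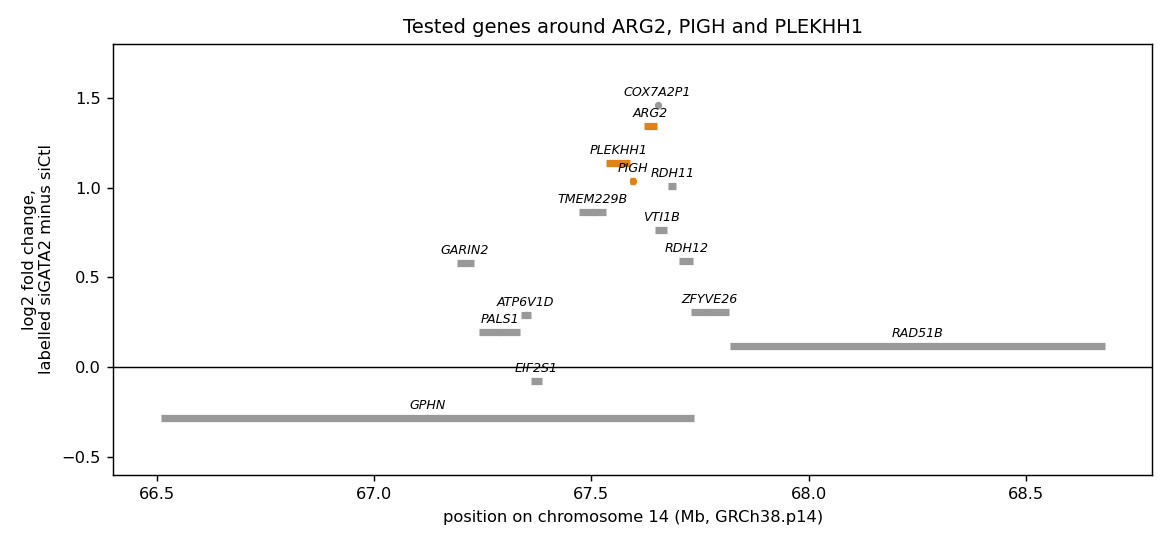
Log2 fold change in the libraries labelled siGATA2 minus siCtl (y axis) against position on chromosome 14 in Mb (x axis); each point is 1 tested gene within 1 Mb of ARG2, PLEKHH1 and PIGH, a region chosen after its values were seen, orange where edgeR called the gene and grey where not. The 3 called genes lie at 1.34, 1.14 and 1.04, and 13 of the 15 genes lie above 0.

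In all, edgeR called 32 genes in the libraries labelled siGATA2, 8 higher and 24 lower (5 and 6 with library totals alone, where PIK3IP1, PIGH, LGMN, RNFT2, RPF1, BTG2, OAS3, SLC1A4 and the pseudogene EEF1A1P6 were no longer called). In the main fit 2166 genes had an unadjusted p under 0.05, and DESeq2 called 535. The main fit takes in the spread of the siAR libraries, between which 1103 genes differed over 2-fold. The libraries labelled siGATA2 had 31 such genes and siCtl 17. With the siAR libraries left out, edgeR on the remaining 4 called 3389, so the low count went with the siAR libraries in the fit.

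In the direct comparison, GATA2 was 1.73-fold lower in the libraries labelled siGATA2 than in siAR (203 ± 15.7 against 351 ± 0.865 CPM, edgeR adjusted p = 0.0315), and AR 2.94-fold higher (783 ± 47.9 against 266 ± 17.5 CPM, edgeR adjusted p = 0.00348). ARG2 was 4.08-fold, ZBTB16 3.51-fold and C1orf116, an androgen-induced gene, 4.36-fold higher. COLCA1 was 21.2-fold, COL5A2 4.86-fold and ACP3, prostatic acid phosphatase, 4.67-fold lower. Androgen-induced targets were higher for 4 of 25, 9 adjusted over the list alone (camera adjusted p = 5.94e-11, adjusted p = 0.541 with an estimated correlation), and interferon genes for 3 of 15, 5 adjusted over the list alone (camera adjusted p = 3.42e-05, adjusted p = 0.217 with an estimated correlation). G1/S genes were lower for 2 of 19, 17 adjusted over the list alone (camera adjusted p = 3.85e-11, adjusted p = 0.529 with an estimated correlation), and p53 targets for 3 of 15, 5 adjusted over the list alone (camera adjusted p = 2.07e-04, adjusted p = 0.529 with an estimated correlation, 0.0745 without siAR replicate 2). NF-kB genes were higher for 2 of 11, 3 adjusted over the list alone (camera adjusted p = 2.20e-05, adjusted p = 0.516 with an estimated correlation, 0.514 without siAR replicate 2). Of 399 genes called by edgeR, 121 were higher and 278 lower (140 and 194 with library totals alone). The count was 4607 and 6286 without siAR replicates 1 and 2, and 0 without either library labelled siGATA2, where 3717 genes had an unadjusted p under 0.05 with all libraries and DESeq2 called 1638.

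The gene sets defined by R1881 and DaroR were then followed in the siRNA libraries, among 14910 genes tested in both tables. AR targets stood higher in siCtl than in DaroR, which was counted apart: KLK3 at 589 and 110.4 CPM, NKX3-1 at 736 and 191 CPM, TMPRSS2 at 465 and 103 CPM. The DaroR sets may therefore not describe the state of the siCtl cells. Of 684 genes at least 2-fold higher with R1881, 18 fell and 6 rose in siAR (Fisher's exact test, 2-sided, adjusted p = 1.03e-07 for the falls). Here camera called the set down (adjusted p = 6.31e-04, adjusted p = 0.0173 with an estimated correlation). Of 588 genes lower with R1881, 18 rose and 3 fell (Fisher's exact adjusted p = 2.12e-05 for the rises), while camera did not call the set (adjusted p = 0.211, adjusted p = 0.584 with an estimated correlation, 5.94e-05 without siAR replicate 1). Of 2901 genes higher in DaroR, 65 rose further and 14 fell in siAR (Fisher's exact adjusted p = 2.20e-13 for the rises; camera adjusted p = 6.09e-05, adjusted p = 0.368 with an estimated correlation, 0.124 without siAR replicate 1). Of 1984 genes lower in DaroR, 27 fell and 11 rose (Fisher's exact adjusted p = 6.98e-06 for the falls; camera adjusted p = 7.32e-04, adjusted p = 0.498 with an estimated correlation, 0.957 without siAR replicate 1). In the libraries labelled siGATA2, 9 of the 1984 genes lower in DaroR fell and 1 rose (Fisher's exact adjusted p = 0.00682 for the falls; camera adjusted p = 3.89e-06, adjusted p = 0.432 with an estimated correlation). The 2901 genes higher in DaroR shifted up (camera adjusted p = 0.0314, adjusted p = 0.498 with an estimated correlation) with 1 called up and 2 down, and lost the call without siCtl replicate 1 (adjusted p = 0.110) or either library labelled siGATA2 (0.0598 and 0.0815). Genes lower with R1881 shifted down (camera adjusted p = 6.61e-10, adjusted p = 0.137 with an estimated correlation) with 1 of 588 called. The genes higher with R1881 shifted up (camera adjusted p = 0.0288, adjusted p = 0.0318 with an estimated correlation), with a median log2 fold change of 0.05, and lost the call without either library labelled siGATA2 (adjusted p = 0.0598 and 0.0725).

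Genes changed in DaroR were then sought among those called in the opposite direction. Of 4783 genes higher in DaroR, 3 were lower in the libraries labelled siGATA2 (7.70 expected by chance) and 3 higher (2.57 expected). The 3 that were lower were RNFT2, SLC1A4, a neutral amino acid transporter (2.06-fold up in DaroR, 1.98-fold down here), and SEPTIN3. Of 4418 genes lower in DaroR, 2 were higher in these libraries (2.37 expected), H2BC21 and BTD, biotinidase, and 15 lower (7.11 expected). BTD was no longer called in DaroR without Vehicle replicate 2 or without the second DaroR column. In siAR, 23 of the genes higher in DaroR were lower (25.3 expected) and 96 higher (43.0 expected), and 23 of those lower in DaroR were higher (39.7 expected) and 38 lower (23.4 expected). The siAR and siGATA2-labelled libraries, compared with the same siCtl, shared 4 genes higher and 4 lower. Independent lists would share 0.0511 and 0.0980, and simulations of unchanged groups gave 0.3 and 0.05. Those simulations hold no changed genes and do not measure the overlap among them. The covariance was 0.286 against a simulated 0.214, and the overlap was 0 without either siCtl library or either library labelled siGATA2, and 13 and 17 without siAR replicates 1 and 2.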

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

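Of the tests in this part, those for admixed cells, exchanged labels, antisense reads, no difference from siCtl, a control under a wrong label, residual AR signalling and a partial fall around the absent genes had their predictions written after the result was seen; the others were written before.

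The rule for flagging looked only at genes named by rule in both comparisons with vehicle, darolutamide at 24 h and DaroR. Those called in opposite directions, with the difference called in the direct comparison, were flagged as a difference between exposure times. Over all genes tested, 194 were called higher at 24 h and lower in DaroR and 209 the reverse, so the flagged genes are a part of these. The log2 fold change of DaroR minus 24 h was 1.997 for AR (-0.60 at 24 h, 1.40 in DaroR), 1.90 for GRHL2 (-0.54, 1.36) and 1.59 for NFKB2 (-0.73, 0.86). It was -5.46 for UGT2B15 (1.33, -4.13), -4.31 for ABCG2 (1.72, -2.59) and -1.41 for NQO1 (0.51, -0.90). The 24 h call of AR was lost without Daro24h replicate 1 (adjusted p = 0.0663). That of GRHL2 was lost without Vehicle replicate 2 (adjusted p = 0.0808) or Daro24h replicate 1 (0.116). That of ABCG2 was lost without Vehicle replicate 2 (0.133), Daro24h replicate 1 (0.10) or Daro24h replicate 2 (0.0551).

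Genes switched off or on in DaroR were weighed first. Of 10 genes over 10 CPM in vehicle and at 0.1 CPM or less in DaroR, 4 had a count of 0 in both DaroR libraries, which argues against admixed cells as the cause. In siCtl, 0% of the 10 were at 1 CPM or more, so different cells in the tables do not account for these absences, but 20% of the 5 gained genes (NTS alone) were under 1 CPM there, and COL3A1 (249 CPM in DaroR, 3.32 and 3.84 CPM in siCtl), KLK2 (50.7 and 719.6 CPM) and FKBP5 (17.4 and 169 CPM) differed between the tables, so a difference between those cells or their culture stays open. The nearest expressed gene was absent for 0 of the 10 (0.0111 on average for random genes), which meets the bound written beforehand against lost stretches, but that bound covers a complete loss alone, and all 10 of these neighbours had a lower value in DaroR, with a median log2 fold change of -1.32 at percentile 0.01 of the neighbours of random genes (middle 95% from -0.81 to 0.32). A partial fall of the wider region, by loss of some copies or by shared silencing, therefore stays open beside the biological hypothesis of silencing or outgrowth of a clone during long exposure. The falls of the neighbours need not be regional, however. Of the neighbours of random genes, 63.0% were lower too, and the 10 lay between 19.8 and 1141 kb from the absent gene. They include NKX3-1 (-1.56), an androgen-induced gene.

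The unchanged GATA2 in the libraries labelled siGATA2 was weighed next. The lowest GATA2 in any siRNA library was 92.4% of siCtl, which argues against labels exchanged within the table. The fit of the 4 libraries alone gave 3389 called genes, so the libraries labelled siGATA2 differed from siCtl beyond the spread within these groups. The 12 false calls set beside this count came from a simulated fit of all siRNA libraries, so they do not calibrate it. Nor does the count show that the siRNA caused the difference. GATA2-AS1 stood at 43.7% and 50.6% of GATA2 in these libraries and was called higher in the fit of 4 libraries (adjusted p = 1.56e-11) but not in the main comparison (adjusted p = 0.239). Antisense reads hiding a fall were left undecided under a rule that was set after the values were seen. It required 50% in both libraries and the main call. With 1 library at 50% or more sufficient and no main call required, the explanation would have been met. A knockdown that acts on protein, or had passed by the time of harvest, could also leave the transcript level, and neither was tested.

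The distance between the siAR libraries was weighed last. The higher AR was 34.2% of siCtl, which argues against a control under a wrong label, 2 genes (FBLN2 and SMOC1) were on in 1 library and off in the other, which argues against wholly different cells but not against a shift in their makeup (markers of AR-negative lines at 34.6 and 6.03 CPM, mostly LAMB3), and the correlation with transcript length was -0.0123, which argues against a length trend. The androgen-induced genes were higher in siAR replicate 2 for 24 of 25 (median log2 ratio 0.90, percentile 100 of random lists, whose middle 95% ran from -0.17 to 0.28). Different residual AR signalling at the same AR transcript level may therefore contribute, but G2/M (0.86), G1/S (0.68) and NF-kB genes (-0.72) differed as well, so the difference was not specific to AR targets. The biological cause was not tested.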

How the results depend on the processing

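The numbers of genes called in the first table stayed within 1.5 times under most alternatives, which does not show that the same genes were called. Of the 9608 genes called in DaroR against vehicle, 8976 were also called with DESeq2 and 7882 with library totals. Of the 1975 called for darolutamide 24 h, 1201 were also called with only the groups compared. Leaving out a library lost some of the calls as well. At adjusted p under 0.01, edgeR called 2798 genes for R1881, 848 for darolutamide 24 h, 19 for siAR, 0 for siGATA2 and 45 for siGATA2 against siAR. With a minimum log2 fold change of 1, the counts were 1356 for R1881, 402 for darolutamide 24 h, 5228 and 5042 for DaroR against vehicle and against darolutamide, 136 for siAR and 186 for siGATA2 against siAR. Fewer genes pass these by construction. With only the groups compared in the fit, 1218 genes were called for darolutamide 24 h, 5 for siAR, 3389 for siGATA2 and 26 for siGATA2 against siAR. DESeq2 called 1430, 535 and 1638 genes in siAR, siGATA2 and their comparison, and edgeR without a count filter 1698, 683 and 1756. For siGATA2, library totals gave 11 genes and the CPM filter 12. The fits of all siRNA libraries take in the spread of the siAR libraries. With only the groups compared, the siRNA counts fell where those libraries stayed and rose to 3389 for siGATA2, where they were left out. The cause of the other changes was not tested.

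With each library left out in turn, genes called ranged from 2535 to 4490 for R1881, 0 to 6818 for siAR, 0 to 0 for siGATA2 and 0 to 6286 for siGATA2 against siAR. The lone library of a group was then assumed to vary like the other groups. The log2 fold change of AR in siAR ranged from -1.66 to -1.53 and was -1.59 with only the groups compared, where it was no longer called. KLK3 turned from 0.98 to -1.64 in siAR and from -1.57 to 1.05 in siGATA2 against siAR, depending on the siAR library kept, and IGFBP3 in siAR from 2.25 to -0.73. The adjusted p of the IGF axis in siAR ranged from 0.0157 to 0.939, and that of G2/M in siGATA2 against siAR from 2.83e-12 to 0.355, with its direction reversed without siAR replicate 2 (0.0146). These follow from the distance between the siAR libraries.

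With an estimated correlation, 2 of 46 gene list calls and 2 of 7 signature calls were kept. This setting also rests on the few residual degrees of freedom, so a lost call does not by itself show correlated genes. For androgen-induced genes with R1881 the estimate was 0.00929, below the preset 0.01, yet the unadjusted camera p went from 4.84e-37 to 2.12e-04. For interferon genes in siAR (0.00867) it went from 9.15e-09 to 0.0102. The overlap of siAR with siGATA2 was 5 genes with the fold minimum, 126 with DESeq2 and 0 to 17 with a library left out. The opposite calls of R1881 and darolutamide were 128 with the fold minimum and 395 to 502 with a library left out, the shared direction of R1881 and DaroR 480 and 1299 to 2632, and that of darolutamide and DaroR 261 with the fold minimum. With a separate control library for each comparison, an alternative chosen after seeing the data, the last became 691 in 1 order of the libraries and that of siAR with siGATA2 became 0 in both orders, where edgeR called no gene in either comparison. For these counts and for AR in siAR and GATA2 in the libraries labelled siGATA2, the alternatives not given here stayed within 1.5 times or on the same side of the threshold. Single lists and signatures crossed it more often. Of 146 list tests, 99 were kept, 17 lost and 30 gained a call with fry, and 102 were kept and 44 lost with an estimated correlation. With a library left out, 539 of 584 list tests were kept, 19 lost and 24 gained a call and 2 reversed, and 40 of 48 signature tests were kept, 7 lost and 1 gained. Of 643 values of named genes, 612 kept direction and call with library totals (20 weaker, 11 stronger), 642 with RLE size factors, 642 without mitochondrial genes (an alternative chosen after seeing the data) and 578 without a filter (64 stronger). With only the groups compared 547 were kept (42 weaker, 54 stronger), and with DESeq2 565 of 623 (3 weaker, 55 stronger). Of 2572 with a library left out, 2198 were kept, 243 became weaker, 128 stronger and 3 reversed.

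With the replicate number as a block (a paired fit), 4878 genes were called for R1881, 2438 for darolutamide 24 h and 282 for siAR, 765 went opposite ways with R1881 and darolutamide, 51 lists and 7 signatures were called, and AR in siAR was at -1.59. The block added calls for p53 targets (0.0496), hypoxia (0.0471) and the IGF axis (0.0471) with R1881, and for G1/S (0.0471) and drug transport (0.0418) in siAR. Same-numbered libraries deviated together with r of 0.0474, 0.0307, -0.00731 and -0.0969, so the numbers were not treated as pairs. No paired analysis was possible because no DaroR or siGATA2 column could be tied to a numbered sample, for the comparisons with those groups.

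On simulated data, 43 of 100 genes at a log2 fold change of 1 were recovered in the siRNA table and 86 of 100 in the other, although the siRNA libraries were the deeper ones, so genes not called there may still have changed. These changed genes were all above a minimum expected count, and recovery of genes with few counts was not measured.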

Other observations

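The prediction for the test in this part was written before its result was seen, but the region was chosen after the values of its called genes were seen.

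ARG2, PLEKHH1 and PIGH, 3 of the 8 genes higher in the libraries labelled siGATA2, are neighbours at 14q24. A change of the whole region was put forward as a hypothesis, and the other 12 tested genes within 1 Mb were examined. Their median log2 fold change was 0.44, at percentile 99.8 of windows with as many genes elsewhere (the limit set beforehand lay at 0.25), so the prediction was met. COX7A2P1 (1.46), RDH11 (1.01), TMEM229B (0.86) and VTI1B (0.76) were the highest. None of the 12 was called by edgeR in the main comparison (0), and 6 were called in the fit of these 4 libraries alone. In siAR, PLEKHH1 stood at 0.77, PIGH at -0.47 and ARG2 at -0.69. Of the highest neighbours, TMEM229B stood at 1.56 and RDH11 at 0.42 in siAR, VTI1B at -0.06 and COX7A2P1 at -0.45. The test could reflect a gain of the region in the transfected cells or shared regulation, and it does not separate these.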
